A study of Mus musculus with 6 samples.

How the data were processed

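Freshly sorted tdTomato-positive and tdTomato-negative cells of adult mouse hind-limb muscle were profiled by RNA sequencing in 6 samples: Tw2pos (n = 2) and Tw2neg (n = 2) from the Twist2 line, and Pax7pos (n = 1) and Pax7neg (n = 1) from the Pax7 line. TopHat2 2.0.0, DESeq2 1.6.3 and the mouse assembly GRCm38/mm10 are named in the submitters' processing notes. The read counter and the gene annotation are not given in the sources used here. The protocol text of the labels describes the sorting of positive cells, and the negative fractions are known from the sample labels.

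The first deposited table holds a normalised signal, called normalised counts here, for 24062 genes in the 4 Twist2 libraries, of which 18503 have a value above 0. Dividing each column by its value of 1 read gave whole numbers for 100% of its values within a tolerance of 0.01, so that reads could be recovered. The second deposited table holds CPM for 4939 genes in both lines, with the Twist2 groups as means of their 2 libraries. Its deposited log2 fold changes equal the log2 ratio of CPM plus 1. Every gene of that table has at least 10 CPM in 3 or more libraries and a deposited difference of at least 2-fold from Tw2neg in 1 or more of 3 comparisons, and all 1964 genes that meet this rule in the Twist2 libraries are in it. The CPM of each Twist2 library was rebuilt from the recovered reads. All columns with samples were mapped. The effective library sizes were 15312683 and 15643678 reads for Tw2neg, 9710688 and 10262454 for Tw2pos, 9572963 for Pax7pos and 12445892 for Pax7neg. The replicates differed by more than counting error: chi-square per degree of freedom was 13.7 over 14349 genes in Tw2pos and 69.6 over 15193 genes in Tw2neg, with Pearson r across genes of 0.982 and 0.963. Genes are not independent replicates.

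The comparison of Tw2pos with Tw2neg was fitted on log2 of the normalised counts plus 1, over genes with a mean of at least 10. The planned fit had 6 libraries; this table holds only the 4 Twist2 libraries, so 4 were used. The comparisons of Tw2pos with Pax7pos and of Tw2neg with Pax7neg were fitted on log2 of CPM plus 1 over all 6 libraries, where the lone Pax7 libraries are assumed to vary like the Twist2 libraries. Both fits used limma 3.58.1 in R 4.3.3 with a mean-variance trend, 2 residual degrees of freedom and Benjamini-Hochberg adjustment, and genes passed at an adjusted p under 0.05. The moderation added 4.00 prior degrees of freedom in the first fit and 5.75 in the second. In fits with 1 Twist2 library left out, the spread came from the pair of the other Twist2 group alone. Pax7pos and Pax7neg were compared by the log2 difference of CPM plus 10, with a size of at least 2 taken as different, and without a test. Group tests used camera with a preset correlation of 0.01, beside an estimated correlation, on lists with at least 3 measured members. In the Pax7 comparison list medians were ranked among 10000 random lists matched on level. As alternatives, edgeR 4.0.16 called 5342 genes between Tw2pos and Tw2neg and 2809 between Tw2pos and Pax7pos on the recovered reads, and DESeq2 1.42.0 was run on the same reads. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

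The 24 gene lists, the tests, thresholds, most of the other settings tried and the rule for named genes were chosen before the data were examined. The lists cover satellite cells, myogenic regulators, myofibres, fibro-adipogenic progenitors, matrix, tendon, mesenchymal transcription factors, interstitial progenitors, endothelium, pericytes, macrophages, lymphocytes, neutrophils, red blood cells, Schwann cells, adipocytes, the Notch, TGF-beta and Wnt pathways, axon guidance, growth factors, complement, the cell cycle and immediate-early genes. The rule names Twist2 and Pax7, the genes whose Cre drove the label, and Twist1, a relative of Twist2. It adds the 6 largest rises and the 6 largest falls past the threshold, with a mean of at least 50 and no overlap between the libraries of the 2 groups, leaving out predicted genes. From each list it takes up to 3 members with the highest mean and the member with the largest passing change in each direction. The Pax7 comparison uses the same rule by size. Some genes that passed are not reported here. Positions are from GENCODE release M21, used only for location, in 1-based coordinates. Genes that share sequence with paralogues or overlap an antisense gene are uncertain, as the strand of the libraries is not given in the sources used here. The floor for genes without reads covers counting error only.

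The scripts were tested on simulated data. Of genes changed 2-fold, 4-fold and 8-fold, 11.9%, 79.1% and 98.5% were recovered in the Tw2pos and Tw2neg comparison (5.97% false calls), 11.9%, 76.1% and 100% in that of Tw2pos and Pax7pos (10.7%), and 8.96%, 82.1% and 100% in that of the unlabelled cells (8.63%). The difference between the lines recovered 2.99%, 31.3% and 75.8%, with 16.1% false calls. Only 67, 67 and 66 genes were changed by these folds, out of 14066 in the first comparison. Library sizes were known, and the lone Pax7 libraries were drawn with the same spread as the Twist2 libraries. In the real data 38.6% and 59.6% of genes passed in the first 2 comparisons, so these rates may not carry over to them. Camera called 0 of 24 unchanged sets with either correlation, and it called a shifted set with the preset correlation only. A call lost with the estimated correlation is therefore not evidence that a list did not differ. The simulated genes varied independently of each other. In the real comparison of Tw2pos with Tw2neg the estimated correlation was 0.94 for matrix and 0.97 for tendon genes. The 0 of 24 therefore says nothing about false calls with the preset correlation on lists whose genes move together.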

Results

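RNA from adult mouse hind-limb muscle cells was sequenced after sorting on a red fluorescent lineage label, tdTomato, which tamoxifen switches on in cells that express Cre recombinase from the Twist2 or the Pax7 gene. Mice received 3 tamoxifen treatments, with muscle taken 10 days later. Twist2 encodes a basic helix-loop-helix factor of mesenchymal cells, and Pax7 marks satellite cells, the stem cells of muscle. The 6 samples fall into 4 groups. Labelled cells of the Twist2 line (Tw2pos) and unlabelled cells of that line (Tw2neg) have 2 libraries each. Labelled cells of the Pax7 line (Pax7pos) and its unlabelled cells (Pax7neg) have 1 library each. The normalised count table lists 24062 genes for the 4 Twist2 libraries. They held 10902318 and 12425426 reads in Tw2pos and 13205751 and 13005707 reads in Tw2neg, with between 16508 and 17350 genes at 1 read or more. The counts-per-million (CPM) table covers 4939 genes that the authors had chosen, and there the Pax7pos library held 6016469 reads and the Pax7neg library 7565797. The 10 most abundant genes took 17.2% and 17.9% of the reads in Tw2pos and 5.98% and 4.91% in Tw2neg. Values below are mean ± SD over the 2 libraries of a group where a group has 2. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

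Twist2 and Pax7, the genes whose Cre drove the label, were examined first, together with Twist1. Twist2 (GRCm38 chromosome 1, 91801461 to 91848028, plus strand) had 161 ± 86.6 normalised counts in Tw2pos and 22.6 ± 0.871 in Tw2neg, a log2 fold change of 2.67 (SE 0.45, limma adjusted p = 0.0071). Its relative Twist1 (chromosome 12, 33957671 to 33959829, plus strand) had 802 ± 56.2 against 131 ± 52.3 normalised counts, with a log2 fold change of 2.66 (SE 0.31, adjusted p = 0.0024). Twist1 stood at 1.57 CPM in Pax7pos, from 15 reads, and at 30.7 CPM in Pax7neg. Pax7 (chromosome 4, 139737062 to 139833528, minus strand) was at 303 CPM in Pax7pos and 0.402 CPM in Pax7neg, the latter from 5 reads. In the Twist2 line Pax7 reached 9.68 ± 3.49 CPM in Tw2pos and 30.3 ± 21.8 CPM in Tw2neg, and that difference did not pass the test (log2 fold change −1.48, SE 0.55, adjusted p = 0.080). Pax7 did pass as lower in Tw2pos with DESeq2 (adjusted p = 0.0049), under library total scaling (0.0204), in the 6-library fit over the CPM table (0.0472) and without Tw2neg replicate 2 (−2.29; 0.0181). All 3 genes are protein-coding. The CPM table has no line for Twist2, so its level in the Pax7 line is not given here.

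**Figure D1:**
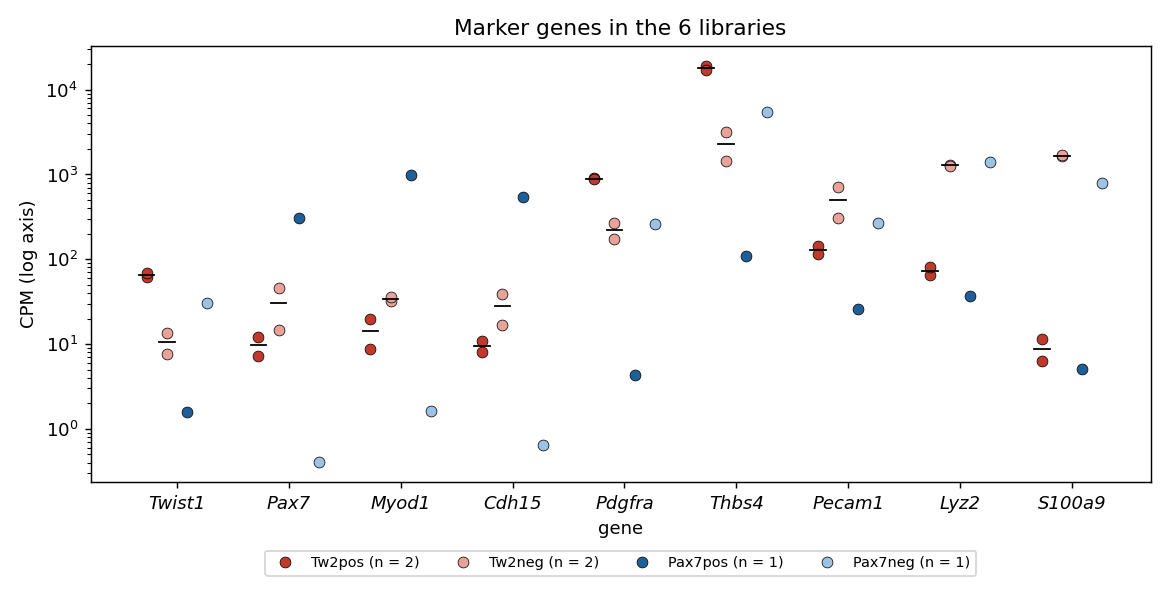
Each point is the CPM of a marker gene (log axis) in 1 library of Tw2pos (n = 2), Tw2neg (n = 2), Pax7pos (n = 1) or Pax7neg (n = 1), with a bar at the mean where n = 2. Pax7, Myod1 and Cdh15 are highest in Pax7pos (303, 993 and 540 CPM), Pdgfra and Thbs4 are highest in Tw2pos, and S100a9 is lowest in the labelled cells of both lines.

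The first comparison set labelled against unlabelled cells of the Twist2 line. Cfd and Col22a1 were among the genes with the largest rises in labelled cells. Cfd, complement factor D (chromosome 10, 79890853 to 79892655, plus strand), had 373 ± 85.6 normalised counts against 6.46 ± 2.36, and Col22a1, a collagen of the muscle-tendon junction (chromosome 15, 71795795 to 72034227, minus strand), had 14434 ± 419 against 628 ± 424. Their log2 fold changes were 5.66 (SE 0.39, limma adjusted p = 0.0005) and 4.71 (SE 0.47, adjusted p = 0.0016). The others were Pnoc, the nociceptin precursor (5.23), C1qtnf4, a secreted C1q and TNF family protein (4.92), Ptprt, a receptor tyrosine phosphatase (4.66), and Fam159b (4.56). The largest falls were in genes of blood cells. Cnr2, the cannabinoid receptor of immune cells, had no reads in either Tw2pos library and 661 ± 368 normalised counts in Tw2neg, which makes it at least 177.6-fold lower than the Tw2neg mean, with a floor of 3 reads per library. Without Tw2neg replicate 2 the bound is 107.7-fold, as replicate 1 had 401 normalised counts of Cnr2. Camp, an antimicrobial peptide of neutrophils, and Ngp, a neutrophil granule protein, had log2 fold changes of −7.95 (SE 0.61) and −7.65 (SE 0.23). Cd177, a neutrophil surface protein, had 17 reads in 1 Tw2pos library and 0 in the other, against 1885 ± 546 normalised counts. Fcnb, a ficolin, and Padi4, a neutrophil arginine deiminase, had 1 and 2 reads over both Tw2pos libraries and means of 337 and 382 normalised counts in Tw2neg. In all, 2645 of 14155 genes tested were higher and 2825 lower in labelled cells (38.6% together). Without Tw2pos replicate 1 the count of both directions fell from 5470 to 2831 genes, without Tw2pos replicate 2 to 2578, and the 6-library fit over the CPM table called 2975 of 4790. The genes of the CPM table had been chosen by the authors partly on this same difference. Its share of calls is therefore not comparable with the 38.6%. The split of 2645 and 2825 moved to 1601 higher and 5289 lower when reads were scaled by library totals. The median of all genes was then −0.50 instead of −0.04, and quantile normalization put that median at 0.10.

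Gene lists fixed in advance describe which programmes differed. Of 23 measured markers of fibro-adipogenic progenitors, the interstitial fibroblasts of muscle, 19 rose and 4 did not pass (21 rose when adjusted over the list alone), among them Mgp, a matrix mineralisation inhibitor (log2 fold change 3.08), and Serpinf1 (2.60). Of 32 matrix genes 29 rose (32 adjusted over the list alone), with periostin, Postn, at 3.11. Of 13 tendon markers 12 rose (13 adjusted over the list alone). Col22a1 was the largest of these rises, and Thbs4, a tendon matrix glycoprotein (chromosome 13, 92751590 to 92794818, minus strand), had 224467 ± 17744 normalised counts against 28690 ± 15127, a log2 fold change of 3.07 (SE 0.69, adjusted p = 0.018). Of 20 mesenchymal transcription factors 14 rose (16 adjusted over the list alone), Prrx1 by 2.45. TGF-beta and BMP genes counted 19 higher, 1 lower and 6 not passed (19 and 2 adjusted over the list alone), with the BMP antagonist Chrdl1 at 2.93 and Tgfb1 at −0.96. Wnt genes counted 16 higher and 2 lower of 23 (17 and 2 adjusted over the list alone), with the secreted regulators Dkk2 and Dkk3 at 2.89 and 2.81 and the lymphocyte and Wnt factor Lef1 at −5.95. Growth factors and chemokines counted 16 higher and 1 lower of 25, unchanged when adjusted over the list alone, with Igf1 at 2.46 and the chemokine Cxcl2 at −2.27. Complement genes counted 10 higher and 1 lower of 13 (11 and 1 adjusted over the list alone), with C2 at 2.59, C7 at 2.41 and Cfp, properdin of myeloid cells, at −2.44. The camera test with a preset correlation called these 8 lists as higher. None of the 8 held with an estimated correlation (adjusted p = 0.512 with an estimated correlation for each).

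Markers of other cell types moved in the opposite direction in the same libraries. All 20 measured macrophage and monocyte markers fell, as did all 15 lymphocyte and all 11 neutrophil markers, with the same numbers adjusted over the list alone. Ptprc (CD45) had a log2 fold change of −5.63, the lysozyme Lyz2 −4.15, the B cell gene Ms4a1 −7.45, and the calgranulin S100a9 −7.63. Of 20 endothelial markers 14 fell (15 adjusted over the list alone), with the vascular receptor Robo4 at −2.81. Of 20 proliferation genes 19 fell (19 adjusted over the list alone), with the cycling marker Mki67 at −3.26. All 3 measured red blood cell genes fell (3 adjusted over the list alone), with the haem synthesis enzyme Alas2 at −5.29, and the globin genes on that list were listed at 0 in these libraries. Camera with the preset correlation called these 6 lists as lower, and with an estimated correlation none held: adjusted p = 0.512 with an estimated correlation for 4 of them, 0.480 for neutrophils and 0.718 for the endothelium. The erythroid call also ended without Tw2neg replicate 1 (adjusted p = 0.0536).

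Satellite cell markers went both ways: of 22, 3 were higher, 4 lower and 15 not passed, with the same numbers adjusted over the list alone. Chodl rose by 2.46 and the chemokine receptor Cxcr4, also expressed by leukocytes, fell with a log2 fold change of −5.21. Myogenic regulators counted 4 higher and 3 lower of 13 (the same adjusted over the list alone), with the cofactor Eya2 at 2.33 and Mef2c at −2.06. Of 22 contractile genes of myofibres 7 rose and 2 fell (7 and 2 adjusted over the list alone), all at low levels: skeletal actin, Acta1, had 266 ± 142 normalised counts against 69.9 ± 25.4 (log2 fold change 1.85, adjusted p = 0.024), and the calcium channel Ryr1 had −1.84. Axon guidance genes counted 10 higher and 4 lower of 25 (12 and 4 adjusted over the list alone), with Epha3 at 3.11, Slit3 at 2.40, netrin 1 (Ntn1) at 2.24 and Sema4d at −4.77. Notch genes counted 2 higher and 7 lower of 18 (the same adjusted over the list alone), with Notch1 at −1.74 and the glycosyltransferase Mfng at −3.47. Schwann cell markers counted 2 higher and 7 lower of 13 (2 and 9 adjusted over the list alone), with myelin basic protein, Mbp, at −2.50. Adipocyte markers counted 3 higher and 2 lower of 8 (4 and 3 adjusted over the list alone), led by Cfd and with the lipase Lipe at −1.94. Interstitial progenitor markers counted 2 higher and 2 lower of 13 (the same adjusted over the list alone), with Gli1 at 1.77 and Kit at −2.91. Their median of 0.18 and mean of −0.14 differed in sign. Of 16 pericyte and smooth muscle genes 2 rose, and 0 adjusted over the list alone. Immediate-early genes, which tissue digestion can induce, counted 3 higher, 1 lower and 18 not passed (0 and 1 adjusted over the list alone). Camera called only the immediate-early list among these 10 (adjusted p = 0.0324; adjusted p = 0.736 with an estimated correlation), and its direction turned under quantile normalization (adjusted p = 0.347). That call also ended without Tw2pos replicate 2 (0.0948), without Tw2neg replicate 2 (0.0532) and in the 6-library fit over the CPM table (0.134).

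Several calls in this comparison ended under another scaling, filter or variance model, or with 1 library left out. Quantile normalization ended the calls and lowered the log2 fold changes of Thbs4 (3.07 to 1.20, adjusted p = 0.172), the collagen Col1a1 (2.82 to 0.94, 0.315) and the proteoglycans Dcn (2.39 to 0.59, 0.420) and Fmod (2.86 to 1.598, 0.0508). Without the filter on level, Col1a1 (0.0629) and Acta1 (0.0510) no longer passed, and without a variance trend Tgfb1 did not (0.0557). Without Tw2pos replicate 2, Thbs4 (0.0783), Col1a1 (0.197), Dcn (0.194), Fmod (0.0524), Acta1 (0.149) and Ryr1 (0.0528) no longer passed. Leaving out Tw2pos replicate 1 ended Thbs4 (0.0669), Col1a1 (0.136), Dcn (0.130) and Ryr1 (0.0703). Leaving out Tw2neg replicate 2 ended Thbs4 (0.0788), Col1a1 (0.173), Dcn (0.0967), Acta1 (0.102) and Tgfb1 (0.0713), and leaving out Tw2neg replicate 1 ended Col1a1 (0.0621) and Dcn (0.0614). The Tgfb1 call was also lost without Tw2pos replicate 1 (0.199) or 2 (0.0502). In these fits with 1 library left out the log2 fold changes were 2.51 to 3.15 for Thbs4, 2.27 to 3.38 for Col1a1, 2.16 to 2.62 for Dcn, 2.95 for Fmod, 1.28 and 1.48 for Acta1, −1.73 and −1.94 for Ryr1 and −0.73 to −1.19 for Tgfb1. Col1a1 and Dcn lost the call whichever library was left out. Some lists that camera had not called passed when 1 library was left out. These were axon guidance without either Tw2pos library (0.0383 without replicate 1 and 0.0331 without replicate 2) or without Tw2neg replicate 1 (0.00363). Schwann, Notch and myofibre genes passed without Tw2pos replicate 1 (0.0120, 0.0488 and 0.00662). Schwann, Notch and satellite cell genes passed without Tw2neg replicate 2 (0.00532, 0.00633 and 0.0187), and pericyte genes without Tw2neg replicate 1 (0.00442). With all libraries, camera called Schwann genes with no filter (0.0383) and quantile normalization (0.0358), axon guidance genes with no filter (0.0383) and library total scaling (0.00585), and myofibre genes with no filter (0.0456), quantile normalization (0.0357) and library total scaling (0.00893).

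The second comparison, the one the series design names, set Twist2-labelled against Pax7-labelled cells. Of the named genes, C7 rose most in Tw2pos. This complement component (chromosome 15, 4988762 to 5063740, minus strand) had 1440 ± 397 CPM in Tw2pos and 1.25 CPM in Pax7pos, from 12 reads, a log2 fold change of 9.29 (SE 0.39). Col22a1 (8.38), the TGF-beta family member Gdf10 (8.10), collagen XIV, Col14a1 (7.68), the matrix protein Cilp (7.66) and myocilin, Myoc (7.50), followed. Among the largest falls was Myod1. This gene, the myogenic determination factor (chromosome 7, 46376474 to 46379099, plus strand), had 14.3 ± 7.80 CPM against 993 CPM, a log2 fold change of −6.13 (SE 0.47, limma adjusted p = 5.99e-05). Further falls were seen for Gal, galanin (−6.33), Fam132b, which encodes erythroferrone (−5.84), M-cadherin, Cdh15 (−5.71), Asb5 (−5.60) and musculin, Msc (−5.22). Pax7 differed by −4.87 (SE 0.64) and Twist1 by 4.68 (SE 0.42). Of 4790 genes tested, 1624 were higher and 1229 lower in Tw2pos (59.6% together). These genes had been selected by the authors on differences from Tw2neg and on 10 CPM in 3 or more libraries. A gene high in Pax7pos alone could not meet that rule. The lone Pax7pos library was assumed to vary like the Twist2 libraries. The count of 2853 became 1635 without Tw2pos replicate 1, 1828 without Tw2pos replicate 2, 1501 among genes with a mean of at least 50 CPM and 1847 after quantile normalization. The split was 852 higher and 995 lower after quantile normalization and 1310 and 1585 with DESeq2, while the median of all genes, 0.41 as deposited, was −0.16 and 0.03 under these and 0.19 with TMM factors.

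Among the lists, 15 of 18 satellite cell markers were lower in Tw2pos and 1 was higher, the surface glycoprotein Cd34 (log2 fold change 3.53), which fibroblasts also carry (15 and 1 adjusted over the list alone). The syndecan Sdc4 was at −1.83 and Notch3 at −3.39. All 13 tendon markers were higher (13 adjusted over the list alone), with Thbs4 at 7.34 and Fmod at 6.88. Of 22 fibro-adipogenic progenitor markers 20 were higher (20 adjusted over the list alone), including the receptor Pdgfra at 895 ± 4.18 CPM against 4.28 CPM (7.41) and Dcn (6.61). Matrix genes counted 29 higher of 32 (29 adjusted over the list alone), with Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) at 4.91 and Col1a2 at 6.27. Endothelial markers, here in the same direction, counted 16 higher of 19 (17 adjusted over the list alone), with Ly6c1 at 4.73, and complement 10 of 11 (10 adjusted over the list alone), with C3 at 6.85. Wnt genes counted 12 higher and 2 lower of 18 and mesenchymal transcription factors 11 higher and 3 lower of 15, the same adjusted over the list alone, with Dkk3 at 6.22 and Ebf2 at 6.96, the latter against 2 reads in Pax7pos. Proliferation genes counted 5 lower of 9 (6 adjusted over the list alone), among them Mki67 at −1.89. Camera with the preset correlation called these 9 lists, and none with an estimated one (adjusted p = 0.745 with an estimated correlation for each). A mean of at least 50 CPM ended the Wnt and mesenchymal calls (adjusted p = 0.0906 for both), and leaving out Tw2pos replicate 2 ended that of Mki67 (0.0544).

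The remaining lists were not called by camera. Pericyte genes counted 7 higher and 1 lower of 9, with Pdgfrb at 4.62. Macrophage markers counted 11 higher and 1 lower of 18, with Csf1r at 2.39, while 0 of 13 lymphocyte and 0 of 10 neutrophil markers passed limma, or when adjusted over the list alone. TGF-beta and BMP genes counted 7 higher of 17, axon guidance genes 10 higher and 4 lower of 17 (Slit3 7.28, Plxna2 −2.68), and growth factors 9 higher and 5 lower of 17 (Fgf7 5.31, Vegfa −2.14). Notch genes counted 2 higher and 6 lower of 13, with the target gene Heyl at −2.98 and Notch1 at −2.09. Myogenic regulators counted 2 higher and 3 lower of 5, with Eya2 at 4.25 and Megf10 at −2.36. Schwann markers counted 2 higher of 5, and immediate-early genes 3 higher and 3 lower of 10, with Socs3 at 1.99 and the heat-shock gene Hsph1 at −2.65. Each of these counts was the same adjusted over the list alone. Interstitial progenitor markers counted 7 higher and 2 lower of 12 (7 and 3 adjusted over the list alone), with Ly6a at 5.47 and the phosphatase Alpl at −3.15. Fewer than 3 members were measured for myofibres (Acta1 −4.78), adipocytes (Fasn −1.18) and red blood cells (Alas2 −1.10, not passed). Alas2 did pass with DESeq2 (0.0052), TMM factors (0.0208), quantile normalization (0.0321), only the 2 groups (0.0395) and without Tw2neg replicate 1 (0.0360) or 2 (0.0340). The Fasn call ended after quantile normalization (0.0571) and without Tw2pos replicate 1 (0.0863) or 2 (0.125). With TMM factors camera did call pericyte (0.0402), Notch (0.0238), TGF-beta and BMP (0.00735) and axon guidance genes (0.0114), and with quantile normalization Notch (0.0460) and TGF-beta and BMP genes (0.00856). Without Tw2pos replicate 1 it called Notch genes (0.00970), TGF-beta and BMP genes (0.00836) and axon guidance genes (0.00955). Without Tw2pos replicate 2 it called those 3 (0.0394, 0.00926 and 0.00902) and pericyte genes (0.00926).

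**Figure D2:**
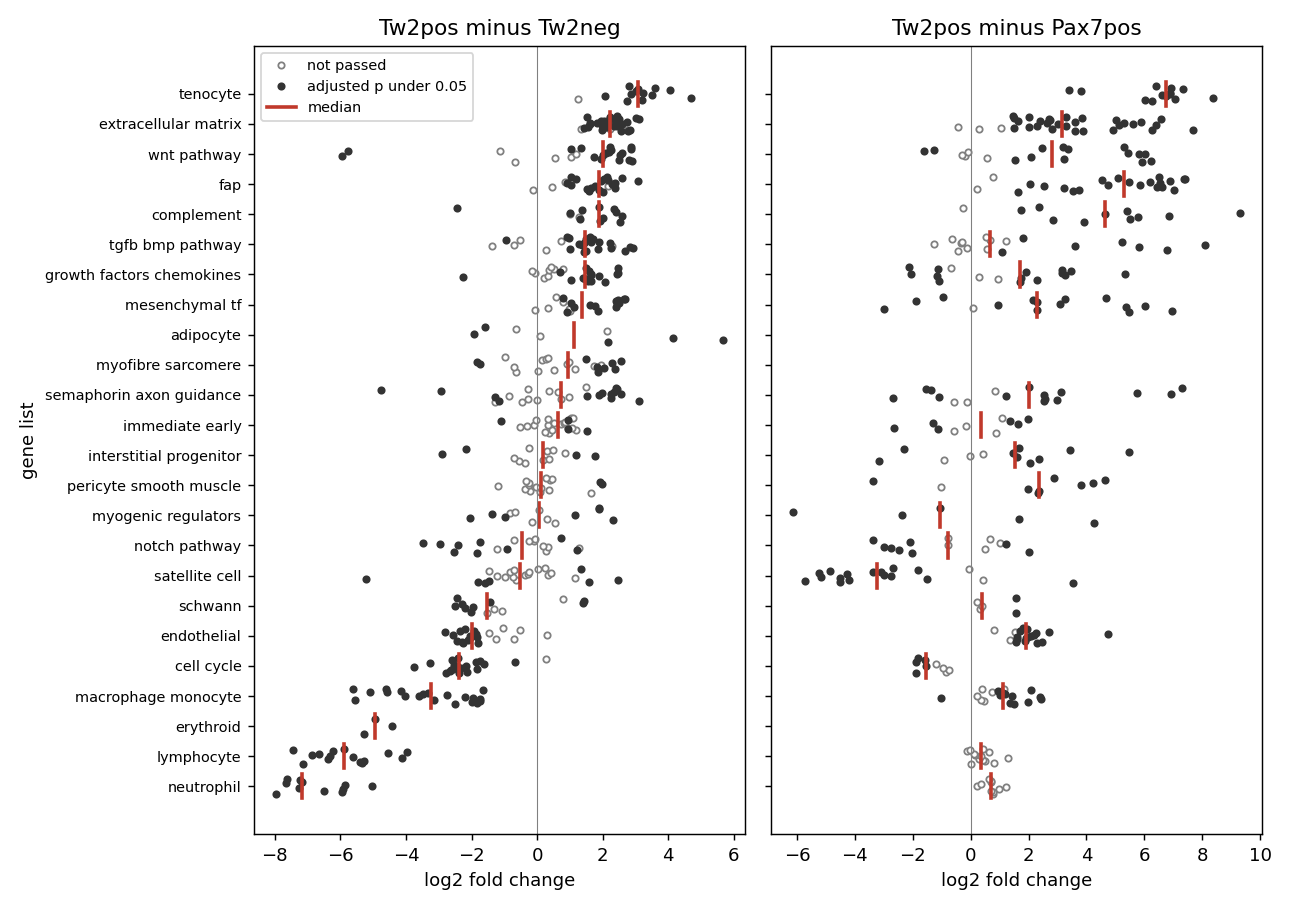
Each point is the log2 fold change of 1 list member in Tw2pos minus Tw2neg (left) or Tw2pos minus Pax7pos (right), filled where the limma adjusted p was under 0.05, with the list median in red and lists ordered by the left median. Neutrophil, lymphocyte and macrophage members lie below 0 on the left (medians −7.18, −5.89 and −3.23), where tendon members have a median of 3.07, and satellite cell members lie mostly below 0 on the right (median −3.25).

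The third comparison set the unlabelled cells of the 2 lines against each other. Tw2neg had lost the Twist2-labelled cells and Pax7neg the Pax7-labelled cells, so effects of the sort and of the line cannot be told apart here. Fam132b stood at 383 ± 119 CPM in Tw2neg and 6.19 CPM in Pax7neg, a log2 fold change of 5.70 (SE 0.40, limma adjusted p = 0.0038). The satellite cell and muscle genes Cdh15 (4.02) and Myod1 (3.75) were also higher in Tw2neg, at 27.9 ± 15.9 and 34.1 ± 3.05 CPM against 0.643 and 1.61 CPM from 8 and 20 reads. Lower in Tw2neg were the pentraxin Ptx3 (−2.83), the protease inhibitor Timp1 (−2.79), the thymosin Tmsb10 (−2.69) and the myeloid nuclear antigen Mnda (−2.63). In total 7 genes were higher and 4 lower of 4790 tested, with 749 at an unadjusted p under 0.05. Also higher, and named only after their values were seen, were Asb5 (4.20), the receptor Fgfr4 (3.99) and Gal (3.74). The 4790 genes had been chosen by the authors partly on the difference between Pax7neg and Tw2neg itself. The counts here and the list results below hold only for genes so chosen. Pax7 itself differed by 4.28 (SE 0.64) and did not pass (adjusted p = 0.051). It passed as higher in Tw2neg with a pseudocount of 0.5 (0.0406), with TMM factors (1.21e-17), with only the 2 groups (4.08e-05) and with DESeq2 (6.87e-11). With 1 Pax7neg library and few residual degrees of freedom, the size of these adjusted p-values is not reliable. The number of calls depended on the method: edgeR called 0 genes, with 711 at an unadjusted p under 0.05, and DESeq2 called 252. TMM factors gave 147 higher and 161 lower genes, and quantile normalization 1 and 0, while the median of all genes was −0.07 as deposited and 0.15 with DESeq2. More genes passed in every fit with 1 library left out. Leaving out a Tw2neg library set 1 library against 1, with the spread taken from the Tw2pos pair alone, so those counts are not given. The median of all genes was −0.10 without Tw2neg replicate 1 and −0.07 without Tw2neg replicate 2. Named genes other than Fam132b lost their calls with a pseudocount of 10, for example Cdh15 (0.147) and Myod1 (0.113), and without a variance trend (0.0833), and all lost them in edgeR (0.0768).

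Lists in the unlabelled cells held few single-gene calls. Satellite cell markers counted 2 higher of 18 and 6 adjusted over the list alone, myogenic regulators 1 of 5 and 2 adjusted over the list alone, and neutrophil markers 0 of 10 and 9 adjusted over the list alone. The neutrophil genes S100a9 and Ngp had 1672.5 ± 11.03 and 1477 ± 212 CPM in Tw2neg against 799 and 541 CPM in Pax7neg. Counts of lower genes were 1 of 32 for matrix (Timp1) and 0 for fibro-adipogenic progenitors, tendon, growth factors and complement. Adjusted over the list alone these were 7, 9, 2, 9 and 5 lower genes. Camera with the preset correlation called these 8 lists and also endothelial (adjusted p = 0.0168) and proliferation genes (0.0175), both as higher in Tw2neg, of which no member passed limma. None held with an estimated correlation (adjusted p = 0.543 with an estimated correlation for neutrophils and 0.835 for the other 9). The endothelial direction turned without Tw2neg replicate 1 (0.822), and without Tw2neg replicate 2 the calls of proliferation genes (0.439) and myogenic regulators (0.0837) ended. A pseudocount of 10 also ended the myogenic call (0.0556). Camera had not called the other 11 lists, and none of their members passed, with 1 interstitial progenitor gene higher when adjusted over the list alone. Left-out Tw2neg replicate 1 made calls for mesenchymal factors, TGF-beta and BMP genes and Wnt genes. Left-out Tw2neg replicate 2 made calls for pericyte, lymphocyte, Notch and axon guidance genes. Those fits set 1 library against 1, with the spread taken from the Tw2pos pair alone. Macrophage (0.0462 and 0.0483) and Notch genes (0.00864 and 0.00853) were called without Tw2pos replicate 1 and 2. These 2 lists were also called with TMM factors (0.0496 and 0.00952) and with only the 2 groups (0.0397 and 0.0113), macrophage genes with a pseudocount of 10 (0.0421), and Wnt genes with no filter (0.0484) and quantile normalization (0.0307).

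The fourth comparison set labelled against unlabelled cells of the Pax7 line. With 1 library against 1 it has no replicate check and no test, and genes were taken by size, an absolute log2 difference of at least 2 on CPM plus 10, which is a 4-fold difference. Fam132b was at 6752 CPM in Pax7pos and 6.19 CPM in Pax7neg (log2 difference 8.71). Asb5 (6.68), Myod1 (6.43), Gal (6.31), the growth factor receptor Fgfr4 (5.70) and Cdh15 (5.69) followed. On the other side stood Col2a1, the cartilage collagen, at 2.92 CPM against 1238 CPM (−6.59), C3 (−6.13), the antigen presentation genes Cd74 (−5.82) and H2-Aa (−5.61), S100a9 (−5.74) and Thbs4 (−5.50). Of 4463 genes, 189 were at least 4-fold higher and 719 at least 4-fold lower in Pax7pos (20.3% together). That count of 908 was 1429 with a pseudocount of 1, 238 with a pseudocount of 50 and 556 among genes with a mean of at least 50 CPM, and quantile normalization gave 279 higher and 494 lower. The median of all genes, −0.29 as deposited, was 0.21 after quantile normalization and −0.13 with TMM factors. Every gene compared had at least 10 CPM in 3 or more of the 6 libraries, so a gene high in Pax7pos alone could not enter. The split and the list percentiles hold only for genes so chosen.

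Of 18 satellite cell markers 13 were at least 4-fold higher in Pax7pos and 1, Cd34 (−2.68), lower, with a median at the 100th percentile of 10000 random lists matched on level. The intermediate filament gene Des was at 5.60, Notch3 at 4.74 and Heyl at 4.04. Of 5 myogenic regulators 3 were higher and 1 lower (percentile 99.95). Blood and vessel markers were lower: 17 of 18 for macrophages, 13 of 13 for lymphocytes, 9 of 9 for neutrophils and 15 of 19 for endothelium, with Ptprc at −5.27. Also lower were 16 of 21 fibro-adipogenic progenitor markers (Dcn −5.46), 11 of 12 tendon, 13 of 32 matrix and 7 of 10 complement genes. Each of those 8 lists had a median at percentile 0. Growth factors (6 of 17 lower, percentile 0.28) and Wnt genes (6 lower and 1 higher of 16, percentile 2.47) were next. The other 9 lists had percentiles between 5.585 and 83.39, among them Notch genes (3 higher and 3 lower of 13, percentile 82.05) and proliferation genes (0 of 11, percentile 83.39). Acta1 was at 576 CPM in Pax7pos and 4.50 CPM in Pax7neg (5.34), and the immediate-early gene Egr1 at 8267 and 1561 CPM (2.40).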

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

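The difference between the 2 lines in the labelled minus unlabelled change was tested with limma over the 6 libraries of the CPM table, a test chosen after the data were seen, and the lone Pax7 libraries were assumed to vary like the Twist2 libraries. The explanations weighed below were also written after the patterns were seen. Of 4790 genes, 1121 had a higher labelled minus unlabelled change in the Twist2 line and 615 a higher one in the Pax7 line. These counts hold only for genes that the authors chose, and they fell without either Tw2pos library. They rose without either Tw2neg library, where the spread came from the Tw2pos pair alone. Of 57 genes named in both comparisons, 33 differed, 24 with the higher change in the Twist2 line and 9 in the Pax7 line. The label marks different cells in the 2 lines, so differences in Pax7 and in cell markers were built into the sort. The 57 genes were also named from these same data, so their number is not independent support.

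The labelled minus unlabelled change was higher in the Pax7 line for Pax7 (log2 difference −9.15), Notch3 (−5.26), Acta1 (−5.01), Mki67 (−3.13) and Alas2 (−2.91). It was also higher there for Notch1 (−2.76), Top2a (−2.61), Sdc4 (−2.08) and Fasn (−1.48). A higher change was not always a rise in labelled cells. Mki67 and Top2a had changes of −0.03 and 0.12 in the Pax7 line and −3.16 and −2.49 in the Twist2 line. Alas2 (−1.75 in the Pax7 line, −4.66 in the Twist2 line) and Klf2 (−3.06 and −1.09) fell in both. The change was higher in the Twist2 line for the matrix and tendon genes Postn (8.94), Thbs4 (8.69), Dcn (7.94), Fmod (7.82), Col1a2 (7.69), Comp (7.51), Col1a1 (6.47) and Col3a1 (4.50). The guidance genes Slit3 (7.80), Ntn1 (2.85) and Nrp1 (2.41), the complement genes C3 (7.63) and Serping1 (3.47), and Sfrp4 (6.96), Serpinf1 (6.70), Ly6a (6.48), Twist1 (6.19), Gsn (5.92), Ebf1 (5.64), Il6 (5.21), Pdgfrb (4.94), Cd34 (4.39), Pmp22 (2.01) and Klf2 (1.97) also differed. Alas2, Top2a, Sdc4, Fasn, Klf2 and Pmp22 lost the call without at least 1 library.

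Tw2pos libraries held satellite cell transcripts. Carry-over of satellite cells would bring other Pax7pos-specific genes at about the share that Pax7 needs, which was 4.01% in Tw2pos replicate 1 and 2.38% in replicate 2. Of 22 such genes, 22.7% lay below 0.5 of that share in replicate 1 and 0 in replicate 2. These genes came from the CPM table, which the authors had limited to genes with a minimum level in several libraries. A gene high in Pax7pos alone could not meet that rule. Genes with low shares in Twist2 cells were therefore partly removed beforehand, and the percentages cannot decide the question. Carry-over was neither ruled out nor shown.

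The 2 Tw2neg libraries differed from each other. A larger lymphocyte share in replicate 2 alone would lower all other cell types by 1 factor, but their list medians spread over a log2 gap of 1.56, from −0.04 for macrophages to −1.61 for pericytes. A wrong scaling factor would move all lists together, but the gap with lymphocytes, at 1.16, was 2.77. In both cases the quartile ranges at the ends did not overlap, which argues against either as the only cause. Part of the pattern also ran between the Tw2pos libraries. Their medians of replicate 2 over replicate 1 were 0.72 for lymphocytes, −0.76 for pericytes and −0.62 for endothelium, in the direction seen in Tw2neg. Satellite cell, fibro-adipogenic progenitor, macrophage and neutrophil medians had opposite signs in Tw2pos and Tw2neg. Both Tw2neg libraries carry the same label, and no other explanation was tested.

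Of 22 contractile genes 7 rose in Tw2pos over Tw2neg, 2 fell and 13 did not pass, and camera did not call the list (adjusted p = 0.0760), though it did with no filter (0.0456), quantile normalization (0.0357) and library total scaling (0.00893). All 7 members that rose were higher in Tw2pos replicate 2 than in replicate 1, with a median log2 ratio of 1.03, at percentile 100 of 10000 random lists matched on level. Genes regulated together would also move together against random lists. The percentile therefore cannot tell RNA from myofibres, in unequal amounts, from expression by the labelled cells themselves. Both stay open, and neither was tested further.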

How the results depend on the processing

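Library total scaling and the fit of 6 libraries over the CPM table were chosen after the data were seen. For Tw2pos against Tw2neg 5470 genes passed. Leaving out 1 library gave 2578 to 7370, and 6 libraries over the CPM table gave 2975, and the fit with only these 2 groups is the fit reported. The 6-library fit covered only 4790 genes, from a table that the authors had chosen partly on this same difference. Other settings gave 4298 to 6890. For Tw2pos against Pax7pos 2853 passed: a mean of at least 50 gave 1501, quantile normalization 1847 and leaving out 1 library 1635 to 3738, with 2630 to 3731 elsewhere. For Tw2neg against Pax7neg 11 passed: a pseudocount of 0.5 gave 17, a pseudocount of 10 gave 1, no filter 3, a mean of at least 50 gave 18, quantile normalization 1, TMM factors 308, no variance trend 1, only the 2 groups 43 and leaving out 1 library 43 to 1038. There edgeR called 0 genes, with 711 at an unadjusted p under 0.05, and DESeq2 252. For Pax7pos against Pax7neg 908 genes differed by size: a pseudocount of 1 gave 1429, a pseudocount of 50 gave 238 and a mean of at least 50 gave 556. The replicate block gave 6627, 3029 and 303 genes in the 3 tested comparisons, sharing 5463, 2819 and 11 of the calls. Among named genes and lists it ended the calls of Col1a1 (0.0547) and the immediate-early list (0.0879) in Tw2pos against Tw2neg, and its other changes of call there were gains, among them Pax7 in Tw2pos against Tw2neg (0.00016) and in Tw2neg against Pax7neg (1.40e-16). The block left fewer residual degrees of freedom than the main fits, so the size of these values is not reliable. The replicates share only a number: across 14155 genes, which are not independent, replicate 1 minus 2 correlated between labelled and unlabelled cells with r = 0.263. The immediate-early list turned direction under quantile normalization in Tw2pos against Tw2neg (adjusted p = 0.347). The endothelial list in Tw2neg vs Pax7neg turned without Tw2neg replicate 1 (0.822; 9.62e-07 without replicate 2). Of named genes called, 63 of 91, 54 of 70, 0 of 7 and 47 of 59 kept the call under every alternative in the 4 comparisons, and of lists called 13 of 15, 7 of 9 and 7 of 10 in the first 3, with the preset correlation. None of these lists held with an estimated correlation (adjusted p of 0.480 or more). Fry, another planned list test, called neutrophil (adjusted p = 0.0012), macrophage (0.0291) and red blood cell genes (0.0291) as lower in Tw2pos than in Tw2neg. Over Pax7pos it called fibro-adipogenic progenitor and complement genes as higher (0.0429 for both). By direction it called no other list in the tested comparisons. The mixed form of fry, which ignores direction, called further lists. Among them were satellite cell (fry mixed adjusted p = 0.0046) and Notch genes (0.0010) in Tw2pos against Tw2neg. Genes not called but called under some alternative numbered 14, 9, 36 and 3. No gene called in both fits changed sign. The cause of these differences was not tested.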

Other observations

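The gene families below were chosen after their values were seen. Hox genes record position along the body and limb, and they were counted by cluster between Tw2pos and Tw2neg, with no test between clusters. All 7 measured Hoxc genes rose (5 under library total scaling), for example Hoxc10 with 452 ± 83.9 normalised counts against 104 ± 34.9 (log2 fold change 2.14, SE 0.31, limma adjusted p = 0.0044). Of 7 Hoxd genes 3 rose, Hoxd8 (1.81), Hoxd11 (2.68) and Hoxd13 (2.40), and 5 did after quantile normalization. Of 9 Hoxa genes 2 rose, Hoxa10 (2.38) and Hoxa11 (1.96), the latter uncertain because of its antisense gene, and 3 did after quantile normalization. None of 8 Hoxb genes passed limma, while 5 were lower under library total scaling. Cartilage collagens differed in another way. Col2a1, the main collagen of cartilage, had 2815 ± 419 normalised counts in Tw2pos and 24276 ± 10818 in Tw2neg (−3.04), and Col9a1 (−3.52), Col9a3 (−3.48), Col10a1 (−2.46) and Col9a2 (−1.91) also fell, 5 of 7 in all. All 7 were higher in Tw2pos than in Pax7pos (6 after quantile normalization), with Col2a1 at 227 ± 33.9 against 2.92 CPM (5.86), and 0 of 7 passed limma between the unlabelled groups.

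Transporters and immune genes were counted in the same way. Of 9 amino acid transporters 8 were lower in Tw2pos than in Pax7pos, such as Slc7a5, a carrier of large neutral amino acids (44.5 ± 11.9 against 611 CPM, log2 fold change −3.78), and Slc38a1 (−3.47). Over Tw2neg they counted 3 higher, 5 lower and 9 not passed of 17 (1 higher and 8 lower under library total scaling), and 0 of 9 passed limma between the unlabelled groups. The interferon-inducible genes Ifi205 (6.53), Ifi203 (5.25) and Ifi204 (5.13) were all higher in Tw2pos than in Pax7pos, and 2 of the 3 were higher than in Tw2neg (Ifi203 0.42, adjusted p = 0.119). Between the unlabelled groups 0 of 3 passed limma, with log2 fold changes of −2.02, −1.53 and −2.14 in Tw2neg over Pax7neg, and all 3 were lower with TMM factors. All 9 MHC class II genes were lower in Tw2pos than in Tw2neg, H2-Aa with a log2 fold change of −5.67, while 0 of 9 passed limma between Tw2pos and Pax7pos or between the unlabelled groups. Adamts proteases and relatives counted 16 higher of 23 in Tw2pos over Tw2neg (11 under library total scaling) and 11 higher and 1 lower of 14 over Pax7pos (8 and 2 after quantile normalization), with 0 of 14 past limma between the unlabelled groups. Ribosomal protein genes counted 39 lower of 42 in Tw2pos against Pax7pos (29 after quantile normalization and 42 with TMM factors). Against Tw2neg 0 were higher, 6 lower and 72 not passed of 78 (27 lower under library total scaling). Between the unlabelled groups 0 of 42 passed limma, with a median log2 fold change of −0.83 in Tw2neg over Pax7neg, and 8 were lower with TMM factors. These counts are uncertain because the genes share reads with paralogues. Those that involve the Pax7 line also hold only for genes that the authors chose.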
